A study of Mus musculus with 2 samples.

How the data were processed

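The series holds CTCF ChIP-seq of stomach tissue from newborn mice (postnatal day 0, strain B6NCrl). ChIP-seq sequences the DNA fragments that an antibody recovers with a protein, and CTCF is the zinc finger protein that binds insulators and the anchors of chromatin loops. There was 1 group with 2 samples, numbered as biological replicates 1 and 2. The labels name a single donor and a single tissue sample for both, so the spread between the replicates, and any value set against it, may be technical. The sex of the tissue was not collected, per the labels. With 1 group, no contrast between conditions was possible. Control libraries are not analysed here.

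The deposited files are 5 peak lists in mm10 coordinates. Per the descriptions deposited with the samples, 3 are relaxed lists (replicate 1, replicate 2, and both together), derived from the alignments and a control alignment. The other 2 are the optimal and the conservative lists after IDR, a procedure that keeps peaks ranked alike in replicates. The aligner, the peak caller, the IDR version and the IDR threshold are not given in the sources used here. The signal of each peak is the authors' own value from their peak caller, is not scaled between lists, and served only to describe and rank peaks within a list. The deposited lists also give −log10 of a q-value per peak, from 0.270 to 5.12 in the optimal list. The score deposited with each peak was 0 throughout the relaxed lists and ran from 537 to 1000 in the optimal list. Each list gives the offset of the summit from the peak start in bp, as deposited. Read numbers were not used here, so the sequencing depth behind a peak is unknown, and each relaxed list held 300000 peaks.

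Sequence came from the mouse reference of the same assembly, and genes from GENCODE release M21. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9. Peaks on the 19 autosomes, X and Y were kept, which left 74283 optimal peaks and set aside 10 on unplaced scaffolds. Replicates were compared through the 74283 peaks of highest signal in each, with a peak shared when a summit of the other replicate lay within 100 bp, and chance came from 100 random placements. Summits within 1 kb of a protein-coding TSS were counted against 1000 random placements on the same chromosomes outside gaps.

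A CTCF motif matrix of 19 positions was built from the 1000 strongest optimal peaks of chromosome 1, of which 995 could be aligned, and applied to the other chromosomes. A window of 50 bp on either side of the summit had the motif when its best score reached 10.05, which 1% of random windows met. The same windows 1 kb away served as control, with an exact sign test. Orientation of neighbouring motifs up to 100 kb apart was set against 10000 permutations of strand within chromosomes. A 30-base B2 SINE stretch, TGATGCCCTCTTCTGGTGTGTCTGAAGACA, was searched within 100 bp of the summit on either strand with at most 6 mismatches. Gene clusters were compared with 1000 random placements of the same span.

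The 14 gene lists were imprinted genes, Hox genes, clustered protocadherins, glandular stomach epithelium, forestomach squamous epithelium, stomach mesenchyme and smooth muscle, intestinal epithelium, liver and pancreas, enteric neurons and glia, blood and immune cells, endothelium, olfactory and vomeronasal receptors, housekeeping genes, and CTCF and cohesin genes. A member counted when an optimal peak lay within 10 kb of a TSS. Each list was set against 10000 random lists of protein-coding genes of the same size, matched on the number of coding TSS within 100 kb, in a two-sided permutation test with Benjamini-Hochberg adjustment over the 14 lists at 0.05. The gene lists, the main tests, their alternatives and the named loci were chosen before the data were examined. Exceptions, chosen after seeing the data, were 2 alternative treatments of the gene lists, the description of peaks with a signal under 10, and the tests of explanations in the closing section, most of which were set before their own result was seen, with those set later named there. Named loci were the 10 peaks of highest signal, up to 3 members of each list with the strongest peak and up to 2 with none in alphabetical order, and 8 landmark loci. Some loci that this rule takes are not reported here. Intervals are exact Clopper-Pearson 95% intervals and cover counting error only, since peaks and genes are not independent replicates.

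The tests of replicate sharing, TSS proximity, motif, orientation, B2 stretch, gene lists and cluster density were checked on simulated data. The Fisher tests of shares were not simulated. With the motif planted in windows, 85.7% of planted copies and 1.24% of other windows were called, over 10000 windows. All planted B2 copies with up to 6 mismatches were found. Among 200 random lists of 200 genes, 5.00% had p under 0.05, over 21853 coding genes. Of lists of 20 genes with peaks planted at 95%, 81% were found. Members of these simulated lists were scattered over the genome. Hox, protocadherin and receptor genes lie side by side and can share a peak, so the test was not checked for such lists. The alternatives tried were other peak lists, distances, score thresholds, overlap rules and random lists, and lists from a single replicate.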

Results

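CTCF binding in newborn mouse stomach was mapped by ChIP-seq in 2 replicates, for which the labels name the same tissue sample. The optimal list of the authors held 74293 peaks, of which 74283 lay on chromosomes, with a median width of 296 bp. Their signal, a value of the authors' peak caller, ran from 4.99 to 677 with a median of 76.6. The stomach at this age holds glandular and squamous epithelium, smooth muscle, enteric nerves, vessels and blood. No comparison between conditions was possible with 1 group, so the comparisons below are between replicates, between sites and the rest of the genome, and between gene groups.

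Most CTCF peaks of either replicate were found in the other, and each of the 10 strongest optimal peaks had a signal in both. The strongest optimal peak lay in an intron of Fam129b (chromosome 2, 32912386 to 32912809, mm10), with a signal of 677, and had signals of 363 and 318 in the replicate 1 and 2 lists. The next lay between genes near Fnbp1l (chromosome 3, 122638588 to 122639055, signal 675), 40794 bp from the TSS of Glrx3 (chromosome 7, 137478223 to 137478640, signal 664), and in a coding exon of Gdf15, which encodes a stress-induced cytokine (chromosome 8, 70629680 to 70630167, signal 656). The remaining members of the 10 strongest lay near Gins4 (signal 653), Iqsec1 (651), Gm16253 (651), Caln1 (649), Pink1 (648) and Gbx1 (648), and all 10 had a CTCF motif.

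Of the 74283 strongest peaks of each replicate, 63827 (85.9%, interval 85.7 to 86.2) had a partner within 100 bp in the other, against 0.615% by chance. Across these shared peaks the signals of the replicates had a Spearman rho of 0.957, computed across peaks, which are not independent replicates. The share was 59.8% among the top 1000, 94.0% among the top 20000 and 52.3% among the top 200000. Of the optimal peaks, 90.4% were found in the replicate 1 top list, 88.6% in the replicate 2 list, 83.2% in both and 4.25% in neither. The conservative list held 72171 peaks on chromosomes, and 65985 optimal peaks (88.83%, interval 88.60 to 89.05) overlapped one. The lists were not nested, since 8298 optimal and 6204 conservative peaks had no partner. The optimal peaks without a conservative partner had a median signal of 21.8, against 96.0 for the others.

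CTCF peaks were more frequent at gene starts and in exons than chance placement. Summits within 1 kb of a protein-coding TSS numbered 11467, or 15.4% of optimal peaks (interval 15.2 to 15.7), 5.82 times the 2.65% of random placements (SD 0.0599). Intergenic summits were 38.9% of peaks against 51.5% of the genome, and intronic ones 48.0% against 43.4%. Untranslated regions held 5.36% of summits against 1.65%, and coding exons held 3.64% against 1.5%. The permutation test gave p = 0.001, the smallest that 1000 placements can give. The share was 14.6% for replicate 2 alone and 16.4% for replicate 1 alone. Outside chromosome 1, 7044 of the peaks near a TSS had no CTCF motif and 3752 had one. The TSS share was 7.88% of peaks with the motif and 32.2% of those without it.

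Most CTCF peaks carried the CTCF motif at the summit. The matrix built from chromosome 1 peaks had the consensus TGGCCACCAGGGGGCACTA, and 47613 of 69457 peaks on other chromosomes (68.6%, interval 68.2 to 68.9) matched it, against 1.86% of windows 1 kb away. Of the matching peaks, 77.2% had the motif centre within 10 bp of the summit. Strong sites carried it most often, with 92.5% of the 13891 strongest peaks and 44.3% of the 13892 weakest, a difference of 48.2 points. The matrix came from the strongest peaks of chromosome 1, and how far this difference depends on that choice was not tested. The p-values of the exact sign test and of Fisher's exact test for these differences were too small to be recorded.

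Peaks shared by the replicates had the motif in 73.0% of cases, and unshared peaks in 38.5%, a difference of 34.5 points by Fisher's exact test, with a p too small to be recorded. Among the 454 optimal peaks with a signal under 10, 4.63% had the motif and 82.6% (interval 78.8 to 86.0) had another optimal summit within 300 bp, against 2.07% of all optimal peaks. The threshold met by 0.1% of random windows lowered the motif share of all peaks to 31.1%.

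**Figure D1:**
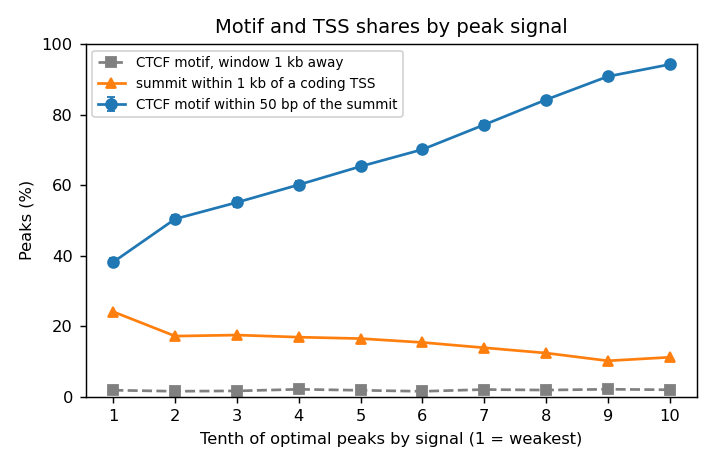
Share of optimal peaks (%) outside chromosome 1 with a CTCF motif within 50 bp of the summit (circles, bars are 95% exact intervals), with the motif 1 kb away (squares), and with the summit within 1 kb of a coding TSS (triangles), in 10 bins of signal. The motif share goes from 38.2% in the weakest bin to 94.2% in the strongest, and the TSS share from 24.1% to 11.2%.

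Neighbouring CTCF motifs up to 100 kb apart faced each other slightly less often than chance over all pairs, with a share that changed with distance. Of 42382 such pairs, 22.8% were convergent (interval 22.4 to 23.2), 24.4% divergent and 52.8% in the same direction, against 25% convergent on permuting strands. The order changed with distance: pairs 1 to 5 kb apart were convergent in 19.2% of cases, the 17780 pairs 20 to 100 kb apart in 25.8% (interval 25.1 to 26.4), and pairs 100 to 1000 kb apart in 30.2% (interval 29.0 to 31.5) and divergent in 17.0%. The two-sided permutation test over all pairs gave p = 1e-04, the smallest that 10000 permutations can give. The ranges of distance given here were not tested one by one. Convergent motifs are known at the anchors of chromatin loops. Loops were not measured in these samples.

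**Figure D2:**
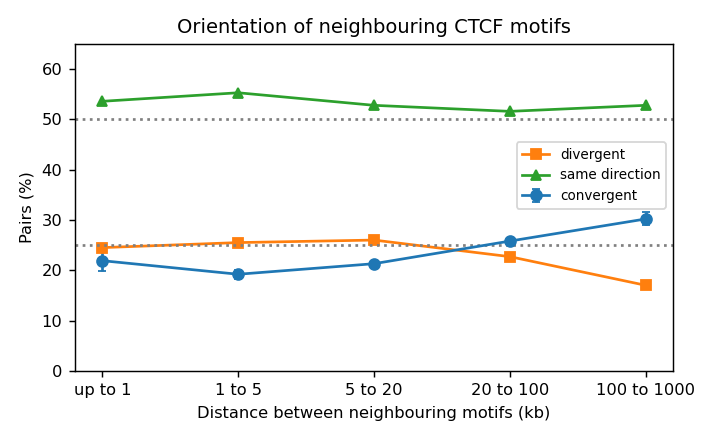
Percentage of neighbouring motif pairs that were convergent (circles, bars are 95% exact intervals), divergent (squares) or in the same direction (triangles), by distance in kb; dotted lines mark 25% and 50%. Convergent pairs rise from 19.2% at 1 to 5 kb to 30.2% at 100 to 1000 kb.

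B2 SINEs, rodent repeats known to carry CTCF sites, were more frequent at weak CTCF peaks and less frequent at strong ones. The B2 stretch lay within 100 bp of 2152 summits (2.90%, interval 2.78 to 3.02), 2.80 times the 1.03% of windows 1 kb away (exact sign test, p = 4.26e-163). The share was 7.20% in the 14857 weakest peaks and 0.0404% in the 14856 strongest. In the stronger 37141 peaks the direction turned, with 0.611% at summits against 1.12% beside them. The genome held 82412 copies of the stretch on the autosomes and X, and 2.66% had an optimal peak within 100 bp. Of these copies, 71.7% reached the motif threshold, so most copies with a motif had no peak. Over all motif matches on the autosomes, 14.9% had an optimal peak within 50 bp.

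Genes of stomach mesenchyme and smooth muscle, enteric neurons and glia, imprinted genes, Hox genes and protocadherins had a CTCF peak near a TSS more often than random genes matched on gene density. Liver and pancreas genes and olfactory and vomeronasal receptors had one less often. Of all 21853 coding genes, 69.7% had a peak within 10 kb. These 7 of the 14 lists passed an adjusted p of 0.05 in the permutation test, with adjusted values given below, and no expression was measured. Of the 7, only protocadherins and receptors kept their call with random lists matched on GC content instead. Protocadherins lost theirs when receptors were left out of the random lists. The signal given for a gene is that of the strongest peak within 10 kb of its TSS, which can lie nearer to another gene.

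In mesenchyme and smooth muscle, 21 of 22 genes had a peak (95.5%, random mean 68.8%, adjusted permutation p = 0.0224), and Nkx2-5 had none. That call was lost with random lists matched on GC content around the TSS (random mean 84.3%, adjusted permutation p = 0.248) and at 1 kb (0.612). The strongest lay 4082 bp from the TSS of Nkx3-2, a homeobox gene of gut mesenchyme (chromosome 5, 41768421 to 41768740, signal 519), followed by Foxf2 (signal 448) and Gli1, a transcription factor of hedgehog signalling (signal 443, in a coding exon of Inhbe). All 15 enteric neuron and glia genes had one (random mean 68.2%, adjusted permutation p = 0.0224), with the strongest 3795 bp from the TSS of Gfap, a glial filament gene (chromosome 11, 102900823 to 102901214, signal 501), then Nos1 (406). That call was lost with GC matching (random mean 78.3%, adjusted permutation p = 0.0678). It was also lost in the strongest 37141 peaks (adjusted permutation p = 0.161, at 73.3% against a random mean of 48.1%). At 1 kb it turned to fewer than random (13.3%, adjusted permutation p = 0.0448). Glandular stomach genes had 23 of 33, at 69.7% against a random mean of 69.6% (adjusted permutation p = 1.00), or of 84.7% with GC matching (0.0678). Muc1, a membrane mucin, had a peak 748 bp from a TSS (chromosome 3, 89228160 to 89228469, signal 467), and Kcne2 and Gkn3 had signals of 424 and 412. Atp4b, a subunit of the acid pump, and Bhlha15 had none. Forestomach squamous genes had 15 of 18 (adjusted permutation p = 0.384), led by Ovol1 (465), Ppl (248) and Krt14 (213), while Dsg3 and Evpl had none.

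Among genes of other organs and cell types, 7 of 17 liver and pancreas genes had a peak (41.2%, random mean 69.7%, adjusted permutation p = 0.0290). That call was lost with GC matching (random mean 60.8%, adjusted permutation p = 0.157) and at 50 kb (0.237). It was also lost in the strongest 37141 peaks (adjusted permutation p = 0.138, at 23.5% against a random mean of 49.3%). Albumin (Alb) and alpha-fetoprotein (Afp) had none, and the strongest were near Cela1 (429), Apoa2 (425) and Ins2 (408). Intestinal genes had 11 of 17 (adjusted permutation p = 0.924), with Tff3 at 451, Fabp2 at 436 and Cdx1 at 425, and none at Cdh17 or Isx. Blood and immune genes had 9 of 18 (adjusted permutation p = 0.0625), led by Cd79a (518), Spi1 (480) and Klf1 (395), with none at Cd4, and passed as fewer than random with GC matching (0.0313), at 1 kb (0.00840) and with receptors left out of the random lists (0.0206). Endothelial genes had 10 of 15 (adjusted permutation p = 1.00), led by Sox18 (525), Pecam1 (294) and Erg (220), with none at Emcn or Flt4, and passed as fewer than random at 1 kb (0.0448). Of 1417 olfactory and vomeronasal receptors, 157 had a peak (11.1%, random mean 70.8%, adjusted permutation p = 0.00140, or 28.7% with GC-matched random lists), with Olfr94 and Olfr95 sharing one of signal 610, Olfr649 at 469, and none at Olfr1 or Olfr10.

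Imprinted genes, expressed from one parental copy, had a peak in 32 of 35 cases (91.4%, random mean 68.1%, adjusted permutation p = 0.0121). The strongest lay near Mcts2 (489), Plagl1 (475) and Airn (456), and Igf2r and Ndn had none. That call was lost with GC matching (random mean 75.7%, adjusted permutation p = 0.0684) and at 1 kb (0.509). Housekeeping genes had 14 of 16 (adjusted permutation p = 0.266), led by Rplp0 (520), Rpl13a (487) and Gusb (417), with none at Hprt or Tbp. Genes of CTCF and the cohesin complex had 16 of 19 (adjusted permutation p = 0.298), led by Esco1 (505), Pds5b (465) and Pds5a (385), with none at Hdac8 or Smc1b. Matching random lists on GC content around the TSS instead left 3 lists past 0.05, namely protocadherins, blood and immune cells, and olfactory and vomeronasal receptors. At 50 kb, where 87.8% of all coding genes had a peak, the imprinted, Hox, mesenchyme and enteric lists stood at 100% and protocadherins at 98.2%, and the measure was at its ceiling, so that distance says nothing on these calls, and the receptors alone passed. At 1 kb, 6 lists passed, of which 3 had the call they have at 10 kb.

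**Figure D3:**
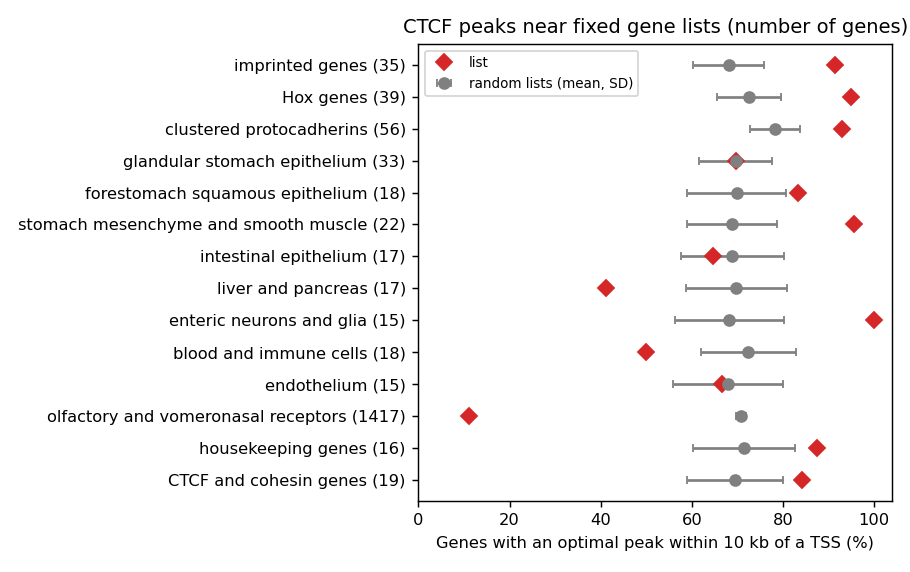
Percentage of genes in each list with an optimal peak within 10 kb of a TSS (diamonds), and the mean and SD of 10000 random lists matched on gene density (circles and bars); the number of genes is in parentheses. Olfactory and vomeronasal receptors lie at 11.1%, below the random mean of 70.8%, which is 28.7% with GC matching.

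The Hox clusters and the protocadherin cluster held many CTCF peaks, but their density did not pass the test. Hox genes, which pattern the body axis, had a peak in 37 of 39 cases (94.9%, random mean 72.5%, adjusted permutation p = 0.00980), with 1 peak of signal 469 in the untranslated region of Hoxa7 (chromosome 6, 52221656 to 52221964) within 10 kb of Hoxa3, Hoxa7 and Hoxa9, and none at Hoxc11 or Hoxd1. Clustered protocadherins, cell adhesion genes of neurons, had 52 of 56 (92.9%, random mean 78.2%, adjusted permutation p = 0.0213), led by a peak of signal 297 that lay 86 bp from the TSS of Pcdhgc3 and 8755 bp from that of Pcdhgc4, and one of 192 that lay 80 bp from Pcdhgb6 and 4979 bp from Pcdhga10, with none at Pcdhac2 or Pcdhb1. The protocadherin span (chromosome 18, 36930184 to 37841873) held 61 peaks, or 66.9 per Mb, and 28 of its 31 motifs were on the plus strand. HoxA held 9 peaks (85.5 per Mb), HoxB 16 (92.0), HoxC 8 (69.1) and HoxD 7 (72.3). These densities were 2.22 to 3.23 times the random mean, with an adjusted p of 0.153 for each in the permutation test. The call for Hox genes ended without replicate 2 (adjusted permutation p = 0.0805), with GC matching (random mean 87.7%, 0.264), with receptors left out of the random lists (0.103), and at 1 kb, where the share was 30.8%, below random (0.449). That for protocadherins ended with receptors left out (adjusted permutation p = 0.162) and in the strongest 37141 peaks, where the share was below random (0.251).

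**Figure D4:**
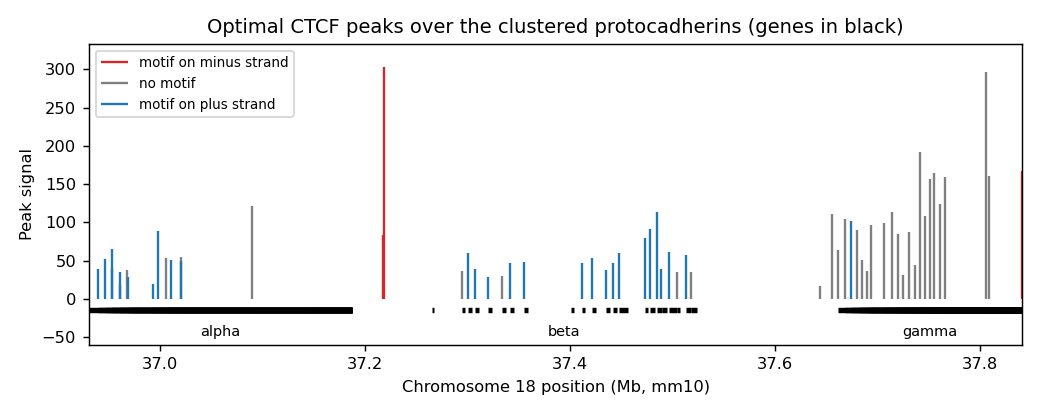
Signal of each optimal peak over the clustered protocadherins on chromosome 18 (position in Mb, mm10), coloured by motif strand, with genes as black bars. Of the 61 peaks in the span, 28 have a plus-strand motif and 3 a minus-strand motif.

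Most of the 8 landmark loci had peaks close to the gene. At H19, an imprinted noncoding RNA, the peak nearest the TSS was 1123 bp away (chromosome 7, 142579189 to 142579345, signal 120), and 5 peaks lay within 10 kb. The peak at Meg3 lay 90 bp from its TSS in a noncoding exon (chromosome 12, 109542068 to 109542292, signal 156). At Peg3 it lay 84 bp away in an untranslated region, had no motif, and had signals of 48.8 in replicate 1 and 5.74 in replicate 2. Xist, the RNA of X inactivation, had a peak at 989 bp in a noncoding exon of Tsix (chromosome X, 103484112 to 103484382, signal 359), and Firre had one at 76 bp in its intron (signal 198). The peak at Myc lay 19 bp from its TSS (chromosome 15, 61985465 to 61985695, signal 200) without a motif. Hbb-bs had its nearest peak 20847 bp away (signal 176), and Pcdha1 had a weak one at 82 bp (signal 20.6).

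The X chromosome had fewer CTCF peaks per length than any autosome. It held 1769 optimal peaks, or 10.8 per Mb of non-gap sequence, against 30.3 on the autosomes, a ratio of 0.358. The ratio was 0.356 in replicate 1 and 0.359 in replicate 2. Single autosomes ran from 23.0 per Mb on chromosome 3 to 45.9 on chromosome 11. Chromosome Y had 0 optimal peaks. Coding genes per Mb on X stood at 0.670 of the autosomes. This comparison is a value without a test.

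**Figure D5:**
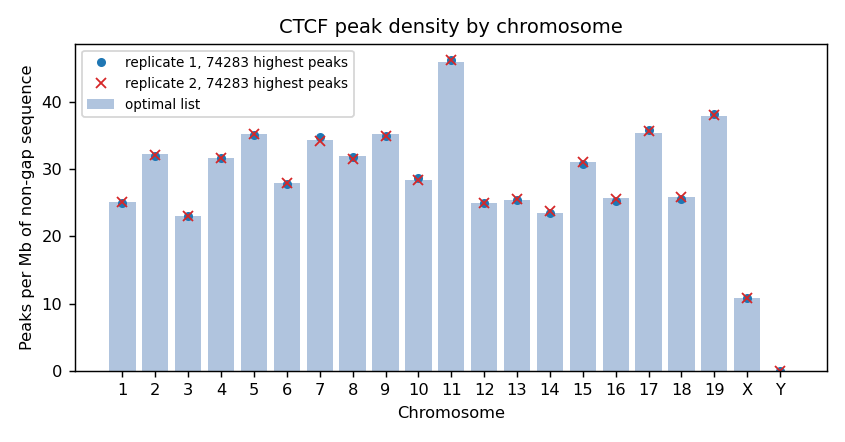
Optimal peaks per Mb of non-gap sequence on each chromosome (bars), with the 74283 strongest peaks of replicate 1 (circles) and replicate 2 (crosses). X lies at 10.8 and the autosomes between 23.0 and 45.9.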

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

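The test of weaker motif matches, the share of all peaks without the motif found in both replicates, and the resampling of the X signal were chosen after the results were seen. Relaxed peaks with no optimal peak within 300 bp were not used in the comparisons, and 15% of the 209544 outside chromosome 1 had the CTCF motif, against 1.84% of windows 1 kb away. A candidate explanation, that part of them are CTCF sites below the IDR threshold, needed over 5% with the motif and had 15%. The share was 44.8% among the 10000 strongest and 6.93% among the 109544 weakest, against 1.77% beside those. Another 10 optimal peaks lay on unplaced scaffolds, a signal outside the chromosomes that were compared.

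The X chromosome held 0.358 times the peak density of the autosomes. Fewer motif matches were argued against as the whole cause, since matches per Mb on X were 0.773 of those on autosomes while 7.61% of X matches had a peak, below the 12.7% to 17.1% of single autosomes. Masked repeat sequence was argued against as the whole cause, since 14.3% of unmasked X matches (interval 13.5 to 15.1) had a peak. Single autosomes had 16.7% to 22.6%. Masked repeats may account for part, as the ratio of X to autosomes went from 0.511 over all matches to 0.720 over unmasked ones. Masking marks repeats in the reference sequence only. Whether reads can be placed was not measured, so unmappable sequence stays open. Lower signal on X cannot be told apart, because the median signal at the strongest X matches, 137 (resampled interval 124 to 147), overlapped the lowest autosome at 133. That was chromosome 5 alone, as the second lowest stood at 149 and the autosomes together at 169. The ratio of X to autosomes in matches with a peak went from 0.475 at the weakest matches to 0.661 at the strongest. Over all optimal peaks, however, the median signal was 87.2 on X and at most 84.6 on an autosome. The sex of the tissue was not collected, and no biological explanation was tested.

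Of the optimal peaks outside chromosome 1, 21844 (31.4%) had no CTCF motif. Calls that do not replicate stay open as a cause. Of these peaks, 69.0% were found in both replicates, against 89.7% of those with the motif. What IDR compared to make the optimal list is not given in the sources used here. Some optimal peaks were found in neither replicate top list, so not every optimal peak was shared by the replicates. IDR may still have raised the share found in both, so a high share cannot argue against that cause. In the weakest of 5 bins of signal the share was 21.1% without the motif against 28.4% with it, a gap of 7.34 points. In 3 bins both shares exceeded 99%. A motif lying wholly at 50 to 150 bp from the summit was argued against, with an excess of 0.0504 points over windows 1 kb away. Motifs across the edge of the summit window fell in neither search, so they stay open. Weaker CTCF matches may account for part of these peaks, since 61.9% had a match over a score met by 10% of random windows, an excess of 50.1 points. Of biological explanations, promoters and sites of other factors were tested separately.

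B2 stretches were 2.80 times as frequent at summits as beside them. Reads shared between near-identical copies were tested through the motif score. Copies in the top 50% of scores had a peak 14.0 times as often as the others, 5.19% against 0.370%. Copies alike in sequence are alike in motif score, so this rise cannot decide on shared reads. The ratio was 17.6 to 40.8 for copies with 2 to 6 mismatches. It was 3.83 with 1 mismatch (3.74% against 0.977%) and could not be computed with 0. Copies with 0 mismatches had a peak in 1.65% of cases and those with 6 in 3.77%. No biological explanation was tested.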

How the results depend on the processing

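The alternatives that restrict the gene lists to coding members or leave receptors out of the random lists were chosen after seeing the data. Of the main results, 47 alternatives left the value within its spread, on its side of the threshold or, for a count, within 1.5 times it, which for gene lists does not mean the same lists: at 1 kb 6 passed, 3 of the main 7 kept their call, 3 lost it, 1 turned and 2 were gained. The share of peaks in both replicates was 84.2% within 50 bp, 87.0% within 250 bp or with 1 bp of overlap, 80.7% with reciprocal overlap, 93.9% over the stronger 50% of peaks and 63.2% over 2 times as many. The correlation was 0.913 over all relaxed peaks with a partner within 100 bp and 0.953 with reciprocal overlap, and the optimal and conservative lists overlapped at 88.51% with reciprocal overlap. The B2 share turned to 0.611% in the strongest 50% of peaks, below its flank. Lists past the threshold numbered 4 in the strongest 50%, 1 at 50 kb, where 8 lists, 4 of the main 7 among them, stood at 100%, and 3 with GC matching. The X ratio was 0.360 in the conservative list, 0.391 in the strongest 50% and 0.447 without repeats. Protocadherins fell below random at 50% in the strongest 50%, and at 1 kb Hox genes did at 30.8% and enteric genes at 13.3%. Leaving out the receptors gave adjusted p of 0.103 for Hox genes and 0.162 for protocadherins. Lists from 1 replicate gave a TSS share of 14.6% to 16.4%, a motif share of 67.7% to 68.3%, a B2 share of 2.52% to 3.16%, and 6 to 7 lists. Depth is unknown, so no limit of detection is given, and the cause of these changes was not tested. No paired analysis was possible because there is 1 group.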

Other observations

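No test in this part was chosen after its result was seen. CTCF peaks without the motif lay at gene starts more often than those with it. Of the 21844 without it, 32.2% (interval 31.6 to 32.9) lay within 1 kb of a coding TSS, against 7.88% of those with it. Named examples were Myc, Peg3, Ppl and Pds5a, each with a peak near its TSS and no motif. Other named genes, Hoxa7, Rplp0, Muc1 and Pcdha1 among them, had a peak within 1 kb of a TSS with the motif.

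A first hypothesis is binding or open chromatin at promoters. The TSS share was higher without the motif in 5 of 5 bins of signal (Fisher's exact test, highest p = 2.19e-71), so the difference in location did not come from signal alone. This gives location only, and neither binding at promoters nor open chromatin was measured, so the hypothesis stays open. The other hypothesis is sites of other factors, and 2 of the 12 listed consensus sequences, those of ETS and NRF1, met the rule fixed for it, NRF1 only because its mirror ratio was 2 and not above, from a mirror share of 0.00458%. The SP/KLF sequence GGGCGGG, at 5.75% of summits against 1.95%, is its own mirror and could not meet the rule. The ETS sequence CCGGAAGT lay at 0.668% of these summits against 0.128% of windows 1 kb away, while its mirror TGAAGGCC had a ratio of 0.927. The mirror has no CG pair and the NRF1 sequence lay at 0.0961% of summits only, so base composition at promoters could give the same values.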
